A study of Zea mays with 12 samples.

How the data were processed

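RNA levels were measured in roots of maize (Zea mays) on 12 Affymetrix arrays. Seedlings grown for 10 days without soil received 5 drops of 20 µL of a spore suspension of Phytophthora cinnamomi, a root-infecting oomycete, or water, per the labels' protocols. Roots were taken at 6 h or 24 h. Each array holds RNA of a pool of 15 plants, and each of 4 groups has 3 arrays. The labels call the repeats technical, although each repeat had its own 60 seedlings, so the p-values measure the spread between these pools. The number of arrays limits the precision.

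The deposited values are log2 levels made by robust multi-chip averaging (RMA) in Partek, per the series' design text and the submitters' processing notes; versions are not given in the sources used here. The log base is not written in the table. The values were read as log2 because RMA gives that scale. No background, normalization or filtering step was added. All 12 sample columns were used.

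The table has 17734 probe sets. The 113 control probe sets with AFFX labels were left out, and 17621 were tested. The platform annotation gave 1 gene for 1452 probe sets, several for 1 and none for 16168. The 1452 stand for 1108 genes, of which 1060 were found by gene ID in the RefSeq table of assembly Zm-B73-REFERENCE-NAM-5.0, and 979 have a name other than a locus number. No coordinates are given because the authors' genome build is not given in the sources used here.

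Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 12 arrays with 4 group means, leaving 8 residual degrees of freedom. Contrasts were tested with lmFit, contrasts.fit and eBayes, and p-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Gene lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, using for each gene the probe set with the highest mean. Of 36 lists, 27 had enough genes, 7 had 1 to 4 genes and 2 had none. The lists, the tests and most alternatives were fixed before the data were examined. List members were found by symbol patterns, and 14 members of 7 lists only have look-alike symbols; the lists were tested again without them.

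Named genes were those with a single-gene probe set past the threshold and no overlap between the groups, up to 12 rises and 12 falls (6 and 6 for the difference and the time comparisons). Where none passed, the 5 smallest unadjusted p in each direction were taken, as values that did not pass. Probe sets without a gene are described, without their identifiers, where a count was 5 or fewer or where they led a comparison, and were chosen after their values were seen.

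In simulated data with the arrays' own noise levels and 200 changed probe sets among 17621, the 6 h comparison recovered 40.4% of changes of 1.5-fold, 70% of 2-fold, 90.4% of 3-fold and 94% of 4-fold, and 1.99% of its calls were false. The 24 h comparison recovered 44.4%, 74%, 88.4% and 94.4%, and 22% of its calls were false, above the threshold of 0.05. One noisy array in the 24 h inoculated group entered that simulation. The simulated noise was independent between probe sets and scaled by 1 factor per array. The real 24 h comparison had 411 unadjusted limma p under 0.05, where evenly spread p-values would give 881. The simulated rates at 24 h therefore may not hold for the real comparison. A shift of 1.5-fold in a list of 12 genes at 6 h was called in 20 of 20 simulations. All 12 genes rose equally there and their noise was independent, a favourable setting that real lists need not meet.

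Replicate numbers pair the samples, because the series text describes each repeat as 1 set of seedlings covering all 4 groups. Deviations from the group means correlated between control and inoculated arrays of the same number by 0.26, 0.12 and 0.3 at 6 h and by 0.2, 0.06 and -0.01 at 24 h. The highest correlations with an array of another number were -0.11, 0.11 and 0.06 at 6 h and 0.19, 0.06 and 0.14 at 24 h. The main fit ignores the pairing, and the main counts below come from it. A fit with the replicate number as a block was run beside it. No pair of arrays was a duplicate: the closest pair had identical values in 0.02% of probe sets.

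The alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 40% of probe sets, a trended robust prior, no shrinkage, the replicate block, array weights, 2 readings of the fold limit of 1.5 in the series text with an unadjusted p, 1 probe set per gene, the 6 arrays of a comparison alone, and leaving out arrays. For lists they were an estimated correlation, fry, all probe sets of the genes, the filter, centring, the block and leaving out arrays. Row labels were checked by comparing levels of probe sets that should measure the same transcript with 2000 shuffles of the levels. This check, and the comparison of the 6 h probe sets at 24 h, were chosen after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.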

Results

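Transcript levels were compared between maize roots inoculated with Phytophthora cinnamomi and water-treated roots, 6 h and 24 h after treatment. Each of the 4 groups had 3 arrays, and each array measured a pool of 15 plants. Median log2 levels lay between 9.27 and 9.33 on 11 arrays. The second inoculated array at 24 h had a median of 9.04 and an SD of 2.06.

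Gene names in this data set carry a limit that applies to each value below. Probe sets assigned to the same gene should have related levels. Over 536 such pairs the correlation of mean log2 level was -0.039, across probe sets and not across samples. Shuffled levels gave -0.082 to 0.086. Pairs from the same transcript subcluster in the same orientation reached 0.088 over 1034 pairs, and 6 of 2000 shuffles were as high. Every other kind of pair examined lay inside its shuffled range. Meanwhile 11 arrays correlated with one another at 0.985 to 0.996. Agreement between rows that share a label was thus absent or weak, although levels repeated between arrays. Genes are named below as the labels give them, and "the row labelled" stands for that limit.

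**Figure D1:**
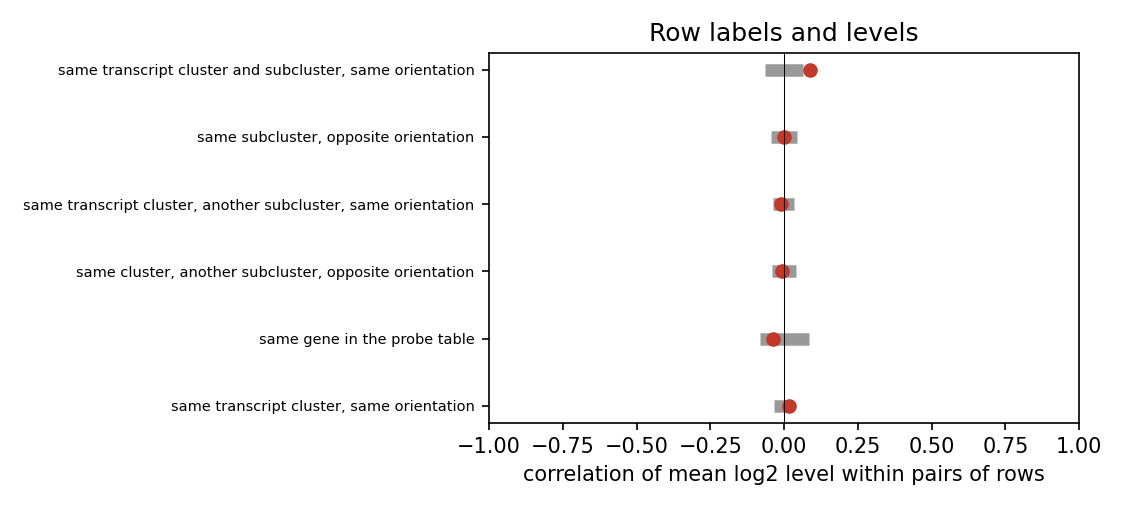
Correlation of mean log2 level (x axis, from -1 to 1) within pairs of probe sets that share a transcript cluster or gene (y axis, kind of pair). Red points are observed values and grey bars the range that 2000 shuffles gave, without their extreme tails; same-gene pairs lie at -0.039, inside the bar.

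At 6 h, inoculated roots differed from controls in 80 of 17621 probe sets, of which 79 were higher and 1 lower (limma, Benjamini-Hochberg adjusted p under 0.05). The median difference of the 80 was 1.53 on the log2 scale, or 2.9-fold, and the largest was 3.32. Every inoculated array lay above or below every control array in all 80. The 80 were chosen on these same arrays, so that separation is no separate support. At an unadjusted p under 0.05 there were 886 probe sets, where evenly spread p-values would give 881. The same fit gave 357 in controls over time, 411 at 24 h and 422 for the difference. It gave 955 for the mean effect and 1050 in inoculated roots over time. The 881 is thus no safe level for no effect here, and the 886 cannot be read as equal to chance. Over all probe sets, 12.1% had groups that did not overlap, and chance gives 10%.

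The row labelled gln1 was the only named gene that met the naming rule at 6 h. Glutamine synthetases, to which gln1 belongs, assimilate ammonium. That row stood at 7.09 ± 0.36 in controls and 10.03 ± 0.26 in inoculated roots (SD, n = 3). The difference was 2.95 ± 0.28 (SE), with a limma adjusted p of 0.0014. It no longer passed without all arrays of replicate 1, with a difference of 2.66 and a limma adjusted p of 0.13, or of replicate 2, with 2.91 and 0.075. Only 3 of the 80 probe sets have a gene in the annotation, which is 3.75% against 8.25% of all probe sets. The other two are rows labelled LOC542286 and LOC732726, with differences of 1.45 and 2.47.

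Among probe sets with no gene, 1 had the smallest p of the comparison. It stood at 8.75 ± 0.34 in controls and 11.16 ± 0.19 in inoculated roots (SD, n = 3). Another unannotated probe set, the leading one averaged over both times, went from 9.08 ± 0.04 to 11.54 ± 0.16 (SD, n = 3). The single lower probe set, also unannotated, went from 8.51 ± 0.02 to 7.87 ± 0.15 (SD, n = 3). Their limma adjusted p were 2e-04, 0.00046 and 0.015. No probe set was called lower without any 1 of the 3 control arrays or without inoculated array 1 or 2 at 6 h, or with the dimmest probe sets left out.

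No fixed gene list passed camera at 6 h. The lists rest on the row labels, whose link to levels was absent or weak. In this and every other comparison, the list tests therefore cannot tell whether a pathway changed or stayed the same. Iron uptake and mugineic acid synthesis had an adjusted p of 0.11, with 5 of its 7 genes above 0 and a median of 0.14. Its adjusted p was 0.53 with an estimated correlation. Nitrate, ammonium and phosphate uptake and assimilation also had an adjusted p of 0.11, and 0.56 with an estimated correlation. Of its 12 genes, 1 passed over all probe sets and 1 adjusted over the list alone, and the median was 0.04. Among seed storage proteins, genes of another organ, 1 of 14 passed adjusted over the list alone, the row labelled z1C1_4 at 1.45 ± 0.33 (SE). The benzoxazinoid pathway, which makes maize defence compounds, had a median of 0.10 over 7 genes and an adjusted p of 0.53.

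The count at 6 h depended on single arrays. It was 33 without control array 1, 53 without control array 3, 34 without inoculated array 1 and 35 without inoculated array 2. Without the second inoculated array at 24 h, which enters only through the shared spread, it was 133. With the replicate block, which takes up the pairing, it was 56.

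At 24 h, no probe set passed limma's threshold between inoculated and control roots. The smallest adjusted p was 0.1, for the unannotated probe set that led the mean over both times, with a difference of 1.58 ± 0.19 (SE). At an unadjusted p under 0.05 there were 411 probe sets, where evenly spread p-values would give 881. Groups did not overlap in 6.7% of all probe sets, below the 10% that chance gives. The second inoculated array at 24 h, which correlated with the others at only 0.944 to 0.957, entered these counts. Its deviations can widen both the spread and the overlap, so the low counts do not show that the roots had no response. The trended prior, the fit without shrinkage, array weights and the replicate block also gave 0. Leaving out the dimmest probe sets gave 1, as did leaving out control array 1.

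Named genes with the smallest p at 24 h did not pass. The row labelled PER42, a class III peroxidase name, stood at 7.42 ± 0.11 in controls and 8.02 ± 0.3 in inoculated roots (SD, n = 3). The row labelled expA4, an expansin name, stood at 8.97 ± 0.16 and 7.89 ± 0.14 (SD, n = 3). Their differences were 0.6 ± 0.16 and -1.08 ± 0.25 (SE), both with a limma adjusted p of 0.79. Rows labelled adf2, FAD8, GIF2 and Lsi6 had differences of 0.33, 0.36, 0.78 and 0.9. Rows labelled sig2A, lbl1, hp2 and mtcpn60II had differences of -0.71, -0.42, -1.36 and -0.37. No list passed, and the smallest adjusted p of the 27 lists was 0.7. Adjusted over the list alone, 1 of 6 class III peroxidases and 1 of 13 expansins and xyloglucan-modifying enzymes passed.

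The 80 probe sets called at 6 h were followed at 24 h. Other arrays measure them there, but through the shared spread those arrays also entered the choice of the probe sets. In inoculated roots 71 were higher than in controls and 9 lower, against a median of 32 higher in 1000 random lists of matched level. Their median difference was 0.21, and random lists gave -0.09 to 0. The random lists were matched on level and not on how probe sets vary together. Their range may therefore be too narrow for probe sets chosen for moving together at 6 h. Averaged per array, the 80 stood at 8.91 ± 0.19 in controls and 10.52 ± 0.09 in inoculated roots at 6 h (SD, n = 3). At 24 h they stood at 9.13 ± 0.02 and 9.49 ± 0.09 (SD, n = 3). An exact two-sided permutation test of the 24 h means gave p = 0.1, the smallest that 3 against 3 arrays allow. Limma's rotation test fry, which asks whether the probe sets moved on balance one way at 24 h, gave an upward direction and 0.0041, a model-based and not a permutation p. The choice favoured probe sets with a small spread at 24 h, so that p and the 24 h SDs may be too small.

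**Figure D2:**
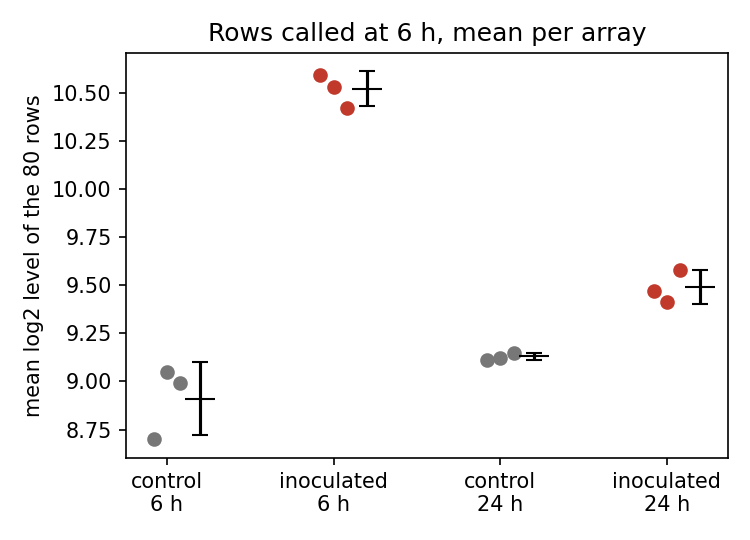
Mean log2 level (y axis) of the 80 probe sets called at 6 h, for each of the 12 arrays by group (x axis). Points are arrays and black bars the group mean and SD; inoculated arrays average 10.52 at 6 h and 9.49 at 24 h, controls 8.91 and 9.13. The 6 h means were used to choose the probe sets, and all 12 arrays entered that choice through the shared spread.

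The inoculation effect differed between the times in 2 probe sets, both smaller at 24 h. Neither has a gene in the annotation. The probe set that led the 6 h comparison differed by -2.13 ± 0.22 (SE), and the next by -1.45 ± 0.16 (SE), with limma adjusted p of 0.022 and 0.028. At 24 h the former stood at 8.89 ± 0.05 in controls and 9.17 ± 0.01 in inoculated roots (SD, n = 3). With the replicate block no probe set passed. Without it 422 had an unadjusted p under 0.05, where evenly spread p-values would give 881. The count was 1 without control array 1 at 6 h. It was 0 without control array 3 or inoculated arrays 1 or 2 at 6 h, without any control array at 24 h, or without inoculated array 1 at 24 h. It was 4 without the second inoculated array at 24 h. The row labelled gln1 had a difference of -2.43 ± 0.4 (SE) and did not pass, with a limma adjusted p of 0.23. No list passed, with a smallest adjusted p of 0.29. Adjusted over the list alone, 1 of 6 class III peroxidases, 1 of 12 nitrate, ammonium and phosphate genes and 1 of 14 seed storage proteins passed.

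Averaged over both times, 48 probe sets were higher in inoculated roots and 0 were lower, with a median difference of 1.18. A large effect at 6 h alone can carry this mean, so these probe sets were not shown to respond at both times. The row labelled gln1 was among the 48, at 1.73 ± 0.2 (SE) and a limma adjusted p of 0.0066. It did not pass without shrinkage, at a difference of 1.73 and an adjusted p of 0.059, or without replicate 1 or 2, at differences of 1.49 and 1.64 and adjusted p of 0.32 and 0.18. Rows labelled LOC542286 and LOC732726 were also among them, at 0.91 and 1.82. With the replicate block 25 passed. Leaving out control arrays 1 or 3 at 6 h gave 30 or 28, and inoculated arrays 1 or 2 at 6 h gave 29 or 24. Leaving out control arrays 2 or 3 at 24 h gave 21 or 20, and inoculated arrays 2 or 3 at 24 h gave 75 or 31. No list passed, with a smallest adjusted p of 0.36, and gln1's list had 1 of 12 genes passing adjusted over the list alone.

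Between 6 h and 24 h, control roots differed in 1 probe set. This unannotated probe set went from 7.45 ± 0.1 to 9.41 ± 0.08 (SD, n = 3), with a limma adjusted p of 0.027. The blocked fit called 2, and leaving out any 1 of the 6 control arrays called 0. Seedling age and hour of day change with harvest time. The row labelled ocl3 went from 9.28 ± 0.13 to 10.73 ± 0.21 (SD, n = 3) and did not pass, with a limma adjusted p of 0.16. Class III peroxidases and the benzoxazinoid pathway each had a camera adjusted p of 0.063, with medians of -0.12 and -0.06. Both had an adjusted p of 0.26 with an estimated correlation. With the replicate block, 1 list passed. Adjusted over the list alone, 1 of 7 genes in the benzoxazinoid list, 1 of 8 dehydrin, LEA and abscisic acid genes and 1 of 14 in the seed storage list passed, the last 2 being the same row, labelled GLB1, at 0.57 ± 0.14 (SE). The first was the row labelled orp2, at -0.73 ± 0.17 (SE), listed by its synonym TSB2, a tryptophan synthase beta name and not that of a benzoxazinoid enzyme.

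In inoculated roots, 22 probe sets differed between the times, 5 higher at 24 h and 17 lower. With the replicate block 13 passed, 6 higher and 7 lower. With array medians centred there were 10 higher and 12 lower, and with quantile normalization 6 higher and 9 lower. The unannotated probe set that led the 6 h comparison fell by 1.99 on the log2 scale, with a limma adjusted p of 0.0014. The count was 5, 3 or 10 without inoculated array 1, 2 or 3 at 6 h, and 4 or 13 without array 1 or 3 at 24 h. Of the 22, 1 has a gene, the row labelled LOC542286, at -1.16 ± 0.15 (SE) and a limma adjusted p of 0.029. No gene with a name met the naming rule. The row labelled gln1 came nearest, at -1.8 ± 0.28 (SE) and a limma adjusted p of 0.051, and the row labelled ocl3 had 1.4 ± 0.23 (SE) and 0.057. No list passed, with a smallest adjusted p of 0.42. Adjusted over the list alone, 3 of 14 genes in the seed storage list passed, 2 higher and 1 lower at 24 h, and 1 each of 7 in the benzoxazinoid list, again orp2, 8 dehydrin, LEA and abscisic acid, and 12 nitrate, ammonium and phosphate genes. The seed storage genes were the row labelled GLB1, with a difference of 0.63, which is also the dehydrin list's gene, z1C1_4, with a difference of -1.47, and zpu1, with a difference of 0.61. The last is the name of a starch-debranching enzyme and not of a storage protein.

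Groups did not separate on the first principal component of the 12 arrays. It held 50.7% of the variance and set the second inoculated array at 24 h, at 81, apart from the others, at -13.6 to -3.7. Without that array the first component held 24%, and the inoculated arrays at 6 h lay at 15.7 to 20.9. The remaining 8 arrays lay at -20.8 to 2.4.

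**Figure D3:**
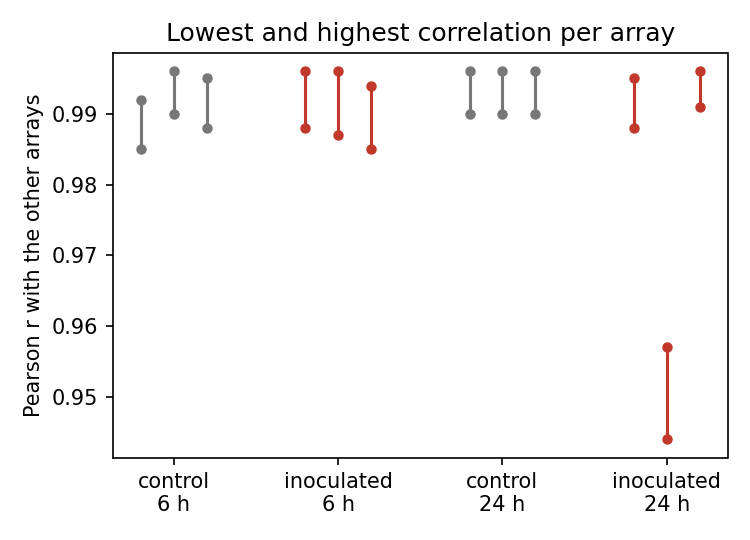
Lowest and highest Pearson correlation (y axis, across probe sets) of each array with the others by group (x axis), leaving out the second inoculated array at 24 h as a partner. That array spans 0.944 to 0.957, and no other array falls below 0.985.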

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

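The explanations in this part, and what each would show, were written down after the results were seen. Their tests were also chosen then, except that the test of the difference and its blocked fit were fixed before. The inoculation effect differed between the times in 2 unannotated probe sets, those with the smallest p at 6 h, by -2.13 and by -1.45, in a test of the difference itself.

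The first pattern is the set of rises at 6 h that were smaller at 24 h. RNA of a pathogen that multiplies on the roots would keep or raise the difference, but its median over the 80 probe sets was 0.21 at 24 h against 1.53 at 6 h. Choosing them at 6 h inflates the 6 h value, and RNA from spores that were later lost stays open. A response of the roots that fades may be a candidate explanation, but 2 probe sets passed the test of the difference and 0 with the replicate block, so it stays open.

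The second pattern is the inoculated array 2 at 24 h. A compressed signal fits its slope of 0.874 on the other arrays but leaves a residual SD of 0.6 around the line, where the other arrays have 0.16 to 0.28, so compression is not the whole cause. A swapped label alone would leave it as close to some group as the other arrays are, at 0.985 or more. Its highest correlation with any array was 0.957, so a swap alone does not account for its distance. Whether its label is also wrong cannot be told, since its mean correlation was 0.954 with its own group and 0.953 with the other groups. Whether that pool responded more strongly stays open. Its mean over the 6 h probe sets was 9.41, against 9.47 and 9.58 in the other inoculated arrays at 24 h, less apart than the group SD of 0.09 from the nearer, and its lower slope also bears on that mean. The spread used to choose those probe sets includes this array, which favours those where it lies near the other 2. The closeness of the means therefore cannot decide the question. Its deviation correlated at -0.004 with the 24 h shift of those 2 arrays. Taken from different control arrays, however, their own shifts correlated with each other at -0.127 to 0.107 and with its shift at -0.096 to 0.134, so no shared 24 h shift was found to hold it against. On the 6 h difference, its shift from the 24 h controls had a slope of 0.44, against 0.21 and 0.24, but a correlation of 0.15, so little of its shift follows the 6 h response. A damaged RNA sample or hybridisation was not tested.

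The third pattern is the missing link between row labels and levels. Labels that belong to other rows are a candidate explanation, since same-gene probe sets correlated at -0.039, inside the shuffled range. The value of 0.088 for subcluster pairs lies above its own range, so some labels may be right. Every other kind of pair examined lay inside its range. All same-orientation cluster pairs, which include the subcluster pairs, had 0.017, inside -0.033 to 0.031. Across arrays, however, subcluster pairs had a median correlation of 0.022, against 0.025 in random pairs. Same-gene pairs had 0.017 against 0.031. That measure showed no agreement, although few probe sets differed between groups, which limits it. Noisy values are argued against by the lowest correlation between arrays, 0.944. Transcript variants and differences between probes stay open: rows of the same bacterial control differed by a median of 2.12 over 18 pairs, inside the 1.21 to 3.54 of random sets of the same structure, but probes of the same sequence can differ in brightness. No biological explanation was tested.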

How the results depend on the processing

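The fits without the inoculated array 2 at 24 h where it is not in the comparison or with the block, lists without look-alike members, and the 24 h follow-up were chosen after seeing the data. The cause of the changes was not tested, except that fewer arrays or probe sets enter some fits. At 6 h the count of 80 became 56 with the replicate block (55 higher, 1 lower), 28 without shrinkage, 154 with array weights, 262 with an unadjusted p and a fold over 1.5, and 133 without the inoculated array 2 at 24 h. Leaving out arrays gave 3 to 59, and leaving out all arrays of replicate 1, 2 or 3 gave 8, 30 or 3. At 24 h the count of 0 became 1 without dim probe sets, 120 with the unadjusted p and fold, and 15 with a log2 difference over 1.5. Leaving out arrays gave 0 to 1. For the difference, the count of 2 became 0 with quantile normalization, without shrinkage, with the replicate block and with the block and without the array apart. It was 1 without dim probe sets or with the trended prior, 5 with array weights, and 236 or 50 by the unadjusted readings. Leaving out arrays gave 0 to 4. For the mean effect, 48 became 8 without shrinkage, 25 with the replicate block, 120 with array weights, and 158 or 26 by the unadjusted readings. Leaving out arrays gave 2 to 75. In controls over time, 1 became 5 with quantile normalization or the 6 arrays alone, 4 with centring, 3 without dim probe sets, 2 with the trended prior or the replicate block and 0 without shrinkage. It became 12 with array weights, 107 or 8 by the unadjusted readings, 8 without the array apart and 11 without it and with the block. Leaving out arrays gave 0. In inoculated roots over time, 22 became 2 without shrinkage or with the 6 arrays alone, 13 with the replicate block, 80 with array weights, 14 with 1 probe set per gene, and 305 or 37 by the unadjusted readings. Leaving out arrays gave 0 to 20. For lists, leaving out arrays at 6 h gave 0 to 1. In controls over time the count of 0 became 2 with all probe sets, 1 with the replicate block and 0 to 2 when arrays were left out. No other list count changed, under the block or without look-alike members. Of 627 values of single probe sets under alternatives, 483 stayed past the threshold, 144 did not and 0 changed sign. The median 24 h difference of the 6 h probe sets stayed between 0.19 and 0.3 whichever 24 h array was left out.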

Other observations

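Other splits of the arrays were counted for each comparison, and what these tests would show was written down after their results were seen. At 6 h the true split called 80 probe sets and the highest of the other splits 1. In inoculated roots over time these were 22 and 0, in controls over time 1 and 0, and at 24 h 0 and 0. With 10 splits of 6 arrays no share under 0.05 can be had; among the splits that part as many pairs the highest was 0 in each. The true split was the 1 split as large in all but the 24 h comparison, where 10 of 10 gave as many. For the mean effect, 1 of 100 splits gave as many as 48, with 27 as the highest other. Among all 32 splits that part every pair, counted later, the true one was again the 1 split as large, a share of 0.031, and the highest other gave 27. Every other split of the 32 with any probe set called keeps the true grouping at 6 h, and those that break it gave 0. The counts therefore carry the 6 h effect, and they do not exclude chance for an effect shared by both times. For the difference, 9 of 100 splits gave at least 2, and the highest other gave 48. All 9 keep the true grouping at 6 h and so carry the 6 h effect, and the 91 that break it gave at most 1. The splits therefore do not settle whether chance gives 2 probe sets for the difference.

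None of the 113 AFFX control probe sets passed limma's threshold at 6 h when fitted with all probe sets, and 8 had an unadjusted p under 0.05. Among the 17621 tested probe sets, 80 passed and 886 had an unadjusted p under 0.05. At that rate few or none of 113 would pass, so the absence of calls says little. The limit on row labels applies to these rows too. The smallest p was that of AFFX-Zm-r2-Ec-bioB-M_at, at 6.24 ± 0.09 in controls and 6.76 ± 0.1 in inoculated roots (SD, n = 3). Its limma adjusted p was 0.062.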
